A study of Homo sapiens with 2 samples.

How the data were processed

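The series holds 2 Affymetrix 3' expression arrays of hTERT-RPE1 cells, 1 for a control oligo and 1 for a miR-129-3p oligo, each hybridised with biotin-labelled cRNA made from 100 ng of total RNA 72 h after transfection, per the labels. Groups were taken from the genotype field of the labels. With n = 1 per group, the 2 arrays limit the precision of every value.

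The deposited table gives 1 intensity per probe set and array for 54613 probe sets, on a linear scale from 1 to 20822, with 0 Affymetrix control probe sets. The submitters' processing notes name MAS5 and RMA, without saying which gave the deposited intensities or how the arrays were scaled to each other; no version, background correction or detection call is given in the sources used here. The 2 columns have similar quartiles (45.0 and 339 in control, 44.9 and 362 with miR-129-3p) but share only 0.49% of their sorted values, so they were not fully quantile-matched. If the low intensities were floored or compressed upstream, differences of dim genes would be affected: 25 and 24 probe sets stand at exactly 1. Spike-in and 3' to 5' ratio checks of RNA quality were planned and not analysed here, since no control probe sets are in the table used.

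Probe sets were named from a platform annotation table. Of the 54613 probe sets, 41091 had 1 gene symbol, 1801 had several and were left out, and 11721 were not listed there and stay unnamed here. The gene IDs of 41037 of the named probe sets matched the reference gene table of GRCh38.p14, from which no coordinates were used. The values proved to be linear, a case the plan allowed for, and were analysed as log2(value + 16), and a difference is the miR-129-3p array minus the control array on that scale, which understates differences of dim genes. Each of 19775 genes was represented by its probe set with the highest mean log2 level, and 12754 genes passed the filter of a signal of 100 or more on the higher array. No test across genes was made and no p-values are given, since genes are not replicates. "Measured" members of a list are those above the filter.

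These choices, 48 gene lists and the rule for named genes were fixed before the data were examined. The rule names the study's target genes whatever their values, the 12 genes with the largest positive and the 12 with the largest negative difference whose other probe sets above the filter go the same way, and per list up to 2 members at each end; uncharacterised gene names are skipped. The target list and the expectation for it come from the series title and the published study. Of 940 list entries 860 had a probe set with a single gene name, and 1 of the 5 study targets was among those not analysed here. For each list, the median log2 difference was set against 10000 random lists of the same size, drawn from the filtered genes with the same numbers in 20 equal bins of mean level. The result of 1 of the 48 lists is not reported here. A list is said to stand apart at percentile 2.5 or less or 97.5 or more; this describes these 2 arrays and is not a test of the conditions.

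Code was tested on simulated data. In 2 simulated arrays, planted log2 differences of 2 and -2 came back with medians of 1.92 and -1.96, and 0.0874% of 12588 unchanged genes passed 2-fold. The simulated noise was smaller than the pooled within-gene SD of 0.37 on the real arrays, and held no spread between cultures. That share is therefore not an error rate for the real counts. For the list percentiles, the real differences were shuffled within level bins over 12754 genes. Of 200 unshifted lists of 20 genes, 7.0% stood apart on either side. Lists shifted upward were counted only when they stood apart as higher. These were 45.5% of lists shifted by 0.25, 98.0% of those shifted by 0.5 and 100% of those shifted by 1.

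Alternatives were median centring, subtraction of a loess trend on level, quantile normalization, no filter, a filter on a mean of 200, the mean of all probe sets of a gene, leaving out probe sets ending in _x_at or _s_at, added constants of 64 and 1, fold limits of 1.5 and 3, 10 bins, and list means. Alternatives added after the data were seen were a floor of 100 on all signals, agreement of all probe sets of a gene, and 5 lists without members shared with other lists. Planned work on miR-129-3p seed matches in 3' UTRs was not run, because no transcript sequences were at hand. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.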

Results

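Gene expression was measured in hTERT-RPE1 cells, a human retinal pigment epithelial line immortalised with telomerase that forms a primary cilium in culture. Cells were transfected with a control oligo or a miR-129-3p oligo by a lipid reagent, and total RNA was taken after 72 h, with 10% fetal bovine serum in the growth medium. Each group held 1 Affymetrix array, so no value below has a replicate error and no difference was tested; a difference compares these 2 arrays, not the conditions. The control array had a median signal of 96.5 and the miR-129-3p array of 98.0 over 54613 probe sets, and 48.9% and 49.4% of probe sets reached a signal of 100. Signals of the 2 arrays correlated with Pearson's r = 0.95 on the log2 scale, across probe sets, which are not independent replicates. Where a gene had several probe sets with signal, their log2 differences had a pooled SD of 0.37 over 6179 genes, a spread within arrays that does not include the spread between cultures.

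The first comparison was over all genes, miR-129-3p against control. The genes with the largest higher difference on the miR-129-3p array included MX1, OAS1 and IFITM1, members of the fixed list of interferon-stimulated genes, and those with the largest lower difference included DIO2, ANKRD1 and TAGLN. Of 12754 genes with a signal of 100 or more on the brighter array, 999 (7.83%) were at least 2-fold higher and 582 (4.56%) at least 2-fold lower with miR-129-3p. At least 4-fold higher were 304 genes, against 118 at least 4-fold lower. At 1.5-fold, the limit of the list counts below, 2210 genes (17.3%) were higher and 1372 (10.8%) lower. Among genes with 2 or more probe sets above the filter, every probe set passed the 2-fold limit for 249 of the 471 genes called higher and for 144 of the 320 called lower. That check was added after the data were seen.

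The 12 genes with the largest higher difference were XAF1, IFI27, MX1, OAS1, IFITM1, RSAD2, MX2, HERC5, RTP4, OASL, BST2 and CMPK2. MX1, a GTPase that blocks virus replication, had a signal of 26.6 in control and 7544 with miR-129-3p, a log2 difference of 7.47. OAS1, an enzyme activated by double-stranded RNA, read 21.8 and 6689, and IFITM1, a membrane protein that restricts virus entry, 94.6 and 15439. All 12 had control signals under 100, where log2 differences depend on the constant added. Set against the filter value of 100 in place of the measured control, they were at least 30.1-fold (RTP4) to at least 154-fold (IFITM1) higher.

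The 12 genes with the largest lower difference fell into different kinds of signal. MAP3K5-AS2, NWD2, TECRL, CDY1 and PRKG1 each rested on a single probe set above the filter, with control signals of 2554 to 5715 and miR-129-3p signals of 3.14 to 34.9. For PRKG1, a cGMP-dependent protein kinase, that probe set read 2554 and 34.9, while its other probe sets read 49.1 and 39.6 in control and 49.1 and 58.4 with miR-129-3p. CEMIP, which takes part in hyaluronan breakdown, read 6048 and 127, but its other probe set with signal differed by only -0.51 on the log2 scale. TAGLN, an actin-binding protein of contractile cells, read 8348 and 641, and its 3 probe sets differed by -3.78 to -2.52. DIO2, a thyroid hormone deiodinase, differed by -3.78 with 5 probe sets between -3.85 and -1.63. ANKRD1, a nuclear cofactor and YAP target, differed by -3.77, and PDGFB, a platelet-derived growth factor chain, by -3.71. FOXS1 (-3.90) and ST6GAL2 (-4.02) completed the 12.

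**Figure D1:**
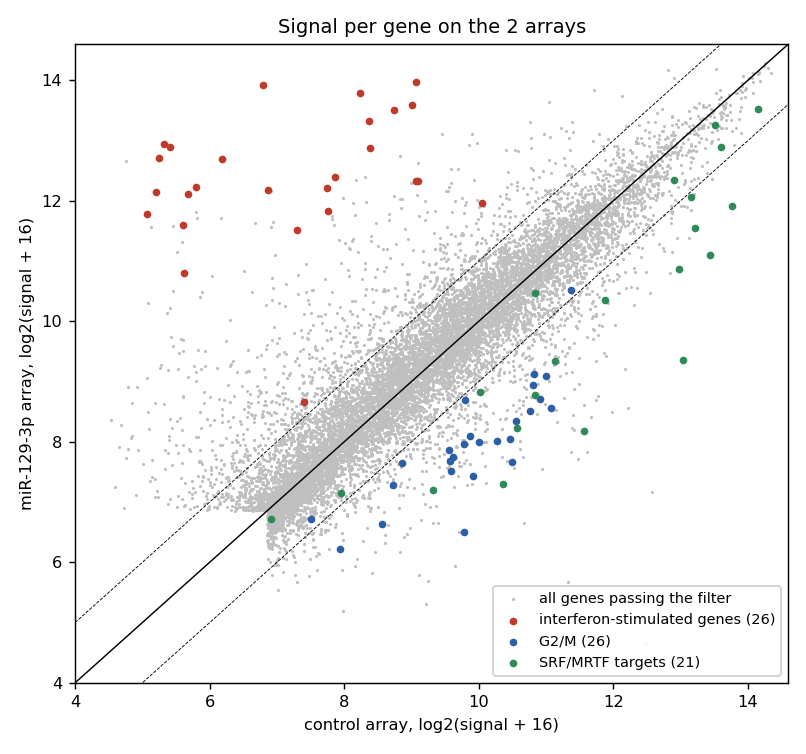
Each point is a gene with a signal of 100 or more on at least 1 array, plotted by its log2(signal + 16) on the control array (x) and the miR-129-3p array (y); the solid line marks equal signals and the dashed lines a 2-fold difference, with 1 array per group. The 26 interferon-stimulated genes lie above the upper dashed line, and the 26 G2/M genes lie below the solid line.

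A further comparison concerned the genes named by the study as regulated by miR-129-3p: CP110, a protein that caps the distal end of centrioles, and regulators of actin. CCP110, which encodes CP110, had a signal of 415 in control and 345 with miR-129-3p on the probe set used, a log2 difference of -0.25 (1.19-fold lower), which is within the spread between probe sets of a gene. Its other probe set was under the filter on both arrays, at 69.9 and 95.1. The arrays read RNA, so the level of the CP110 protein was not measured here. ABLIM1, an actin-binding LIM protein, was lower on both of its probe sets, by -1.24 on the brighter (1066 against 441) and by -1.71 on the other (661 against 191). FNBP1L, also called TOCA1, which activates N-WASP-driven actin assembly, had a difference of -0.91 (1012 against 532). ABLIM3 differed by -0.21 (491 against 424). Of the 5 genes fixed for this list 4 were measured here, all 4 were below 0 and 2 were at least 1.5-fold lower. Their median was -0.58, at percentile 2.02 of 10000 random lists of the same size matched on signal level, whose central 95% ran from -0.54 to 0.76. The percentile rose to 2.60 with a stricter signal filter, past the limit of 2.5 set for a list to stand apart. The study may have chosen these genes with these arrays, so the list is not independent evidence of its direction.

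**Figure D2:**
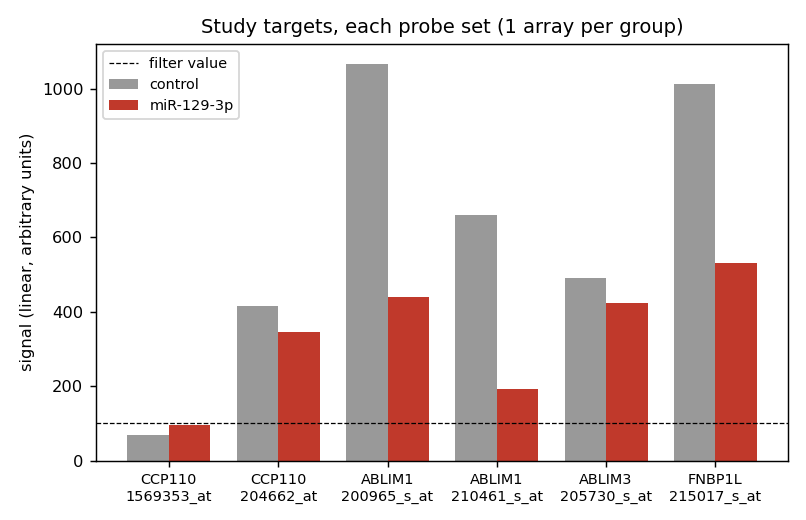
Bars give the linear signal (y, arbitrary units) of every named probe set of CCP110, ABLIM1, ABLIM3 and FNBP1L on the control and the miR-129-3p array, 1 array each; the dashed line is the filter value of 100. Both ABLIM1 probe sets and the FNBP1L probe set were lower with miR-129-3p, and 1 of the 2 CCP110 probe sets was under the filter value on both arrays, so its difference is not read.

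Genes of the centriole and the cilium were compared as lists fixed before the data were examined, and with the settings fixed then none of the 12 lists stood apart from matched random lists. The CP110 partners and brakes on ciliogenesis had a median log2 difference of 0.03 (percentile 41.7), with 2 of 14 measured members at least 1.5-fold lower and 0 higher. CCNF, the cyclin F gene whose product targets CP110 for degradation, differed by -0.93, CETN2, a centrin, by -0.81, and TTBK2, a kinase required to start ciliogenesis, by 0.57. Centriole duplication genes had a median of 0.03 (percentile 40.2) and went both ways: 4 of 19 were at least 1.5-fold higher and 5 lower, among them PLK4, the kinase that starts duplication (-1.16 and -1.14 on its 2 probe sets above the filter), and NEK2 (-2.49, but -0.21 on its other probe set). The pericentriolar and satellite list had a median of 0.02 (percentile 37.1), with NIN, a subdistal appendage protein, at -0.68, and the appendage list one of -0.09 (percentile 23.2).

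The intraflagellar transport genes that build the axoneme differed little as a group. IFT-B genes had a median of -0.05 (percentile 19.8), with 1 of 16 members, IFT57, at least 1.5-fold higher (0.93) and 0 lower. IFT-A genes and their motors had a median of 0.11 (percentile 58.6), with 5 of 14 at least 1.5-fold higher, led by WDR19 (0.95), and 1 lower, DYNC2I2 (724 against 353). The BBSome and RAB8 list stood at 0.16 (percentile 74.1), with ARL6 at 1.32 and EHD1 at 0.95. Transition zone genes had the highest median of these lists, 0.28 (percentile 93.6), with 5 of 21 at least 1.5-fold higher, including TMEM67 (1.02) and AHI1 (0.95), and 1 lower, TMEM237 (-1.18). The list for cilium membrane and axoneme had a median of 0.02 (percentile 43.8) and the motile cilium list, with 5 measured members, one of 0.08 (percentile 64.4). Cilium disassembly genes had a median of -0.10 (percentile 18.6), with 5 of 13 at least 1.5-fold lower, led by NEK2 (-2.49) and AURKA (-2.41), the Aurora A kinase that also acts in mitosis, and 3 higher, led by HDAC6 (0.70). Over the alternatives tried the percentile of this list ranged from 0.19 to 75.5, the latter without the members it shares with the G2/M list, which was chosen after the data were seen. In the Hedgehog pathway, which signals through the primary cilium, the median was -0.07 (percentile 23.4). GLI2, a transcription factor of the pathway, differed by -2.61 on its brightest probe set but by 0.03 on another, HHIP by -2.11, DISP1 by 1.84 and CDON by 1.12.

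Actin genes were compared because the study concerns actin dynamics. Genes of stress fibres and of the transcriptional programmes of SRF and YAP had lower signals with miR-129-3p, while actin nucleators as a group did not stand apart. Of 21 measured targets of SRF and its actin-sensing cofactor MRTF, 17 were at least 1.5-fold lower and 0 higher, with a median of -1.67, below all 10000 random lists (percentile 0.00). Examples are TAGLN (-3.67) and MYL9, a myosin light chain (-3.37, and -1.29 on its other probe set). Of 27 genes of stress fibres and focal adhesions, 16 were at least 1.5-fold lower and 0 higher (median -0.89, percentile 0.00); PTK2, the focal adhesion kinase, had the largest positive difference at 0.55, with one of its other probe sets at -0.22. Among 22 YAP/TEAD targets, 12 were at least 1.5-fold lower and 0 higher (median -0.69, percentile 0.00), with ANKRD1 at -3.77 and CCN1, also called CYR61, at -2.11. The SRF list shared 6 measured members with the stress fibre list and 2 with the YAP/TEAD list, and both of those stayed under percentile 2.5 without the shared members, a setting chosen after the data were seen.

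The 9 measured members of the Arp2/3 complex, which nucleates branched actin, were all below 0, with a median of -0.27 (percentile 5.22), and the list did not stand apart. ARPC4 was at -0.62 and at -1.02 on its other probe set, and ACTR3 at -0.40 on its brightest probe set, with its 5 probe sets between -1.14 and -0.40. Nucleation promoters and formins had a median of 0.05 (percentile 49.98), with DIAPH3, a formin, at -1.83, FMNL2 at 0.83 and WASL, which encodes N-WASP, at 0.81. Severing and capping proteins had a median of -0.13 (percentile 7.23), with 7 of 24 at least 1.5-fold lower, such as CAP2 (-1.31) and CFL2, a cofilin (-0.84), and 2 higher: SCIN (2.93, from a control signal of 14.63) and TESK2 (1.28). Tubulins and microtubule regulators had 12 of 19 members at least 1.5-fold lower and 1 higher (median -0.74, percentile 0.00), led by TUBB2A (-1.67). STMN1, the microtubule destabiliser stathmin, differed by -1.65 on its brighter probe set but by 0.45 on its other probe set.

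Proliferation genes had lower signals with miR-129-3p. All 26 measured G2/M genes were at least 1.5-fold lower, with a median of -1.90 (3.74-fold lower), below all 10000 random lists (percentile 0.00). KIF20A, a mitotic kinesin, differed by -3.27 and CDC20, an activator of the anaphase-promoting complex, by -2.82. Of 25 genes of G1/S and DNA replication, 20 were at least 1.5-fold lower and 0 higher (median -0.87, percentile 0.00), with RRM2, a ribonucleotide reductase subunit, at -1.77 and MCM6, of the replicative helicase, at -1.76. PCNA, the sliding clamp, stood at 0.36. Targets of p53 were higher as a group: 13 of 20 were at least 1.5-fold higher and 3 lower (median 0.69, above all 10000 random lists). GDF15, a stress-induced cytokine, read 14.4 in control and 462 with miR-129-3p on its probe set above the filter, but 29.3 and 27.0, and 71.9 and 60.8, on its others; DDB2 differed by 1.98, ZMAT3 by -1.22 and PLK2 by -1.04. CDKN1A, the CDK inhibitor p21 and a member of both lists, differed by 1.64 (2085 against 6523), while the CDK inhibitor and quiescence list as a whole had a median of -0.07 (percentile 24.5). Of 12 replication-dependent histone genes fixed for a list, 6 were measured. Of these, 5 were at least 1.5-fold higher (median 2.27, percentile 100), including H2AC6 (4.17) and H2BC5 (3.42). Over the alternatives the median of this list ranged from 1.38 to 2.31. Histone genes are near-identical copies, so their probe sets can share transcripts. How fully 3' arrays capture histone transcripts was not tested, so these signals are not a measure of total histone RNA.

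Interferon-stimulated genes showed the largest group difference. All 26 measured members were at least 1.5-fold higher, with a median of 5.06 (33.3-fold on this scale), above all 10000 random lists, whose central 95% ran from -0.16 to 0.32. With all signals under 100 set to 100, an alternative added after the data were seen, the median was 4.83. The smallest difference in the list was 1.26, for OAS2, named after its values were seen. All 12 measured genes of antigen presentation were above 0, 10 of them at least 1.5-fold higher (median 1.65, percentile 100), led by PSMB9, an immunoproteasome subunit (3.30), and TAP1, a peptide transporter (3.22). In the NF-kappaB and inflammatory list 10 of 18 were at least 1.5-fold higher and 1 lower (median 0.95, percentile 100). CCL5, a chemokine, read 39.5 and 3580 and IL1B 208 and 3311, whereas CCL2, another chemokine, read 4033 and 346. IFNB1, which encodes interferon beta, was under the filter on both arrays, at 20.4 and 82.7, and CXCL10 likewise at 24.0 and 79.5; both were chosen after their values were seen. Markers of blood cells had a median of -0.12 over the 3 members above the filter (percentile 38.1). Neuronal markers, fixed as a list for an absent cell type, had a median of 0.56 over 6 members (percentile 98.3) and so stood apart as higher. Over the alternatives the percentile ranged from 55.2 to 99.8. Its members MAP2 and TUBB3, which differed in opposite directions, had control signals of 854 and 4706, so not all its genes were absent here.

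**Figure D3:**
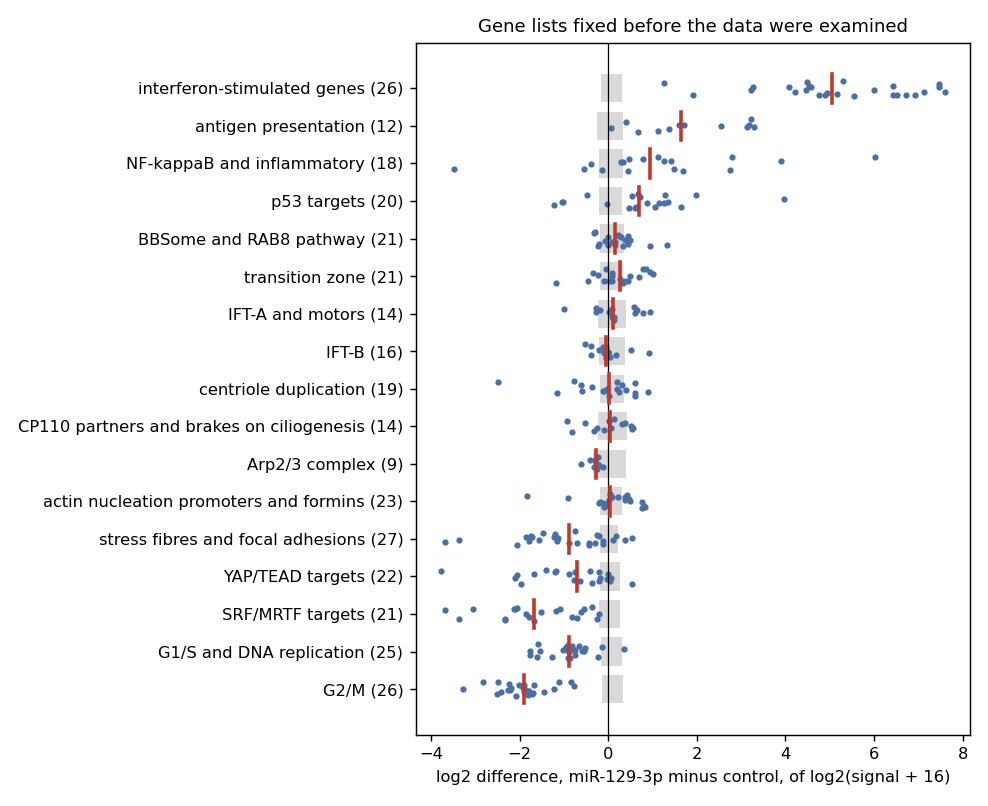
Points are the log2 differences (x, miR-129-3p minus control, of log2(signal + 16)) of the measured members of 17 gene lists (y, number of members in brackets), red ticks are list medians, and grey bars the central 95% of the medians of 10000 matched random lists; 1 array per group. The medians of the interferon (5.06), G2/M (-1.90) and SRF/MRTF (-1.67) lists lie outside their grey bars, and the 6 lists of centriole and cilium genes lie inside theirs.

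Across all 48 lists, 9 stood apart as higher and 12 as lower. At the limits used, 2.4 of the 48 would be expected to stand apart if all were random draws of genes. The lists share members and are not independent.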

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

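The tests of scaling, of blood cell markers, of the number of oligos and of other probe sets of the interferon-stimulated genes, and the counts of G2/M probe sets with other filters, were chosen after the results were seen. Probe sets that have no single gene name, which enter no comparison of the report, also carried signal: of 5075 with a signal of 100 or more on the brighter array, 294 (5.79%) were at least 2-fold higher with miR-129-3p than in control and 177 (3.49%) at least 2-fold lower.

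The interferon-stimulated genes were higher with miR-129-3p by a list median of 5.06. A scaling difference or intensity trend is argued against by its small size: the loess trend on level ran from -0.15 to 0.07 over all probe sets. With so small a trend the 3 scalings could hardly move the list median (lowest 5.02), so their result adds no separate evidence. Cross-hybridisation of single probe sets is argued against as well, since 9 of 9 other probe sets of these genes with a control signal of 100 or more (100%), and 18 of 19 with no filter, were at least 2-fold higher. RNA from blood cells would bring their abundant transcripts, yet 0 of 10 blood cell markers reached 100 with a 2-fold higher signal; the highest marker signal on the miR-129-3p array was 149, for HBB, against 162 in control. What stays open is whether the sequence of miR-129-3p, sensing of this oligo preparation, or a difference between the 2 cultures came with the response, which cannot be told apart with 1 oligo compared with the control.

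The G2/M genes were lower with miR-129-3p by a list median of -1.90. Scaling is argued against by the same small trend, and the median closest to 0 over the same 3 scalings, -1.89, adds no separate evidence. Single faulty probe sets are argued against by 18 of 20 other probe sets above the filter (90.0%) at least 1.5-fold lower. Among those at 100 or more on the miR-129-3p array, a choice that works against a lower call, 12 of 13 were. With no filter the count was 22 of 30, where 10 were under 100 on both arrays and 4 of those were lower by that much. A lower share of dividing cells with miR-129-3p is a biological hypothesis that was not tested.

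A separate pattern is a set of 11 probe sets at 1000 or more on the control array and under 50 on the other, with control signals of 2308 to 5715 and miR-129-3p signals of 3.14 to 34.9, of which 5 have a gene name (MAP3K5-AS2, NWD2, TECRL, CDY1 and PRKG1). The opposite case, 1000 or more with miR-129-3p and under 50 in control, held 33 probe sets, 32 with a gene name, at 1094 to 7815 against 7.47 to 49.4. A local fault of the control array is a candidate explanation that cannot be told apart from a real difference: 0 other probe sets of these genes passed the filter, where 5 were needed for a share. Among the named genes only PRKG1 had other probe sets, at 49.1 and 39.6 in control and 49.1 and 58.4 with miR-129-3p. The filter left these out, so the check could not use probe sets without signal. No biological explanation was tested.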

How the results depend on the processing

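No paired analysis was possible because each group holds 1 array, and for the same reason leaving out a replicate could not be run; the seed-site alternatives were not run for want of transcript sequences. Of 21 lists that stood apart, 16 did so under every alternative tried, among them the interferon (medians 4.81 to 5.26), G2/M (-1.97 to -1.72), SRF/MRTF (-1.78 to -1.57) and p53 (0.62 to 0.73) lists. The floor of 100, the demand for several probe sets and the removal of shared members were chosen after seeing the data, and the cause was not tested for any change below. The 2-fold counts of 999 and 582 became 2210 and 1372 at 1.5-fold, 473 and 221 at 3-fold, and 249 and 144 when 2 or more probe sets all had to pass, which tests fewer genes; elsewhere they stayed within 1.5 times, and CCP110 lay between -0.34 and -0.23. With a mean filter of 200, the study targets (-0.58) and matrix proteases (0.32) no longer stood apart, while heat shock (0.38) and epithelial genes (-0.59) did. With means over probe sets, lysosome (0.17) no longer stood apart and ribosomal proteins (-0.22) did. Without _x_at and _s_at probe sets, lysosome (0.27), matrix proteases (0.32) and neuronal markers (0.90) no longer stood apart and cilium disassembly (-0.42) did, and STMN1 reversed to 0.45. By list mean, lysosome (0.38), matrix proteases (0.28) and neuronal markers (0.45) no longer stood apart, and cilium disassembly (-0.59) and epithelial genes (-0.34) did. Neuronal markers reversed to -0.034 without a filter and reached 0.29 with signals floored at 100. Without members shared with the SRF/MRTF and YAP/TEAD lists, TGF-beta targets (-0.15) no longer stood apart. Of 1624 values of other named genes under alternatives, 89 moved by more than the pooled probe-set SD. A reversal was counted only where the main log2 difference was at least 1 in size, and 1 value reversed. Sign changes of smaller differences were not counted as reversals. Signals near 100 and below have no detection call here, so differences from such levels are bounds at best.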

Other observations

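Further gene lists fixed before the data were examined were compared in the same way. Matrix genes were lower as a group: 11 of 26 fibrillar and basement membrane genes were at least 1.5-fold lower and 4 higher (median -0.47, percentile 0.00). POSTN, a matricellular protein, differed by -3.06 (one probe set at -0.33) and DCN, a proteoglycan, by -1.76, while COL3A1 was at 1.54 and LAMA4 at 1.10. TGF-beta targets had 10 of 20 members at least 1.5-fold lower and 4 higher (median -0.53, percentile 0.00), with TGFB2 at -2.07 and ID2 at 1.91, but stood at -0.15 (percentile 8.52) without members shared with the SRF/MRTF and YAP/TEAD lists, a setting chosen after the data were seen. Matrix proteases and inhibitors had a median of 0.43 (percentile 99.3), with PLAUR, the urokinase receptor, at 1.44, PLAT at 1.40 and ADAM12 at -1.93 (-0.13 on one probe set), and its percentile ranged from 87.4 to 99.4 over the alternatives. Cholesterol synthesis genes had 4 of 16 at least 1.5-fold lower and 0 higher (median -0.38, percentile 0.11), including HMGCS1 (-0.97) and FDPS (-0.87). Metallothioneins, which share near-identical sequence, had 5 of 6 at least 1.5-fold lower (median -0.90, percentile 0.01), with MT1F at -1.05. Hypoxia and glycolysis genes had 7 of 23 at least 1.5-fold higher and 0 lower (median 0.27, percentile 99.6), with NDRG1 at 2.03 and HK2 at 1.54, though at -0.17 on its other probe set. Lysosomal genes had 6 of 22 at least 1.5-fold higher and 0 lower (median 0.31, percentile 98.5), with CTSL, a cathepsin, at 2.22 and GLA at 1.55, and its percentile ranged from 86.1 to 99.6 over the alternatives.

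Within other lists, members went apart. Among immediate early genes (median 0.19, percentile 84.3), the MAP kinase phosphatases DUSP4 (3.33) and DUSP6 (2.83) had higher signals, on 3 probe sets each, and the transcription factors EGR3 (-2.22) and EGR1 (-1.78) lower ones. In the ATF4 and unfolded protein list (median 0.16, percentile 84.0), DDIT3, also called CHOP, stood at 1.30, and the amino acid synthesis genes PSAT1 and ASNS at -2.53 and -2.06. The retinal pigment epithelium markers had a median of 0.18 (percentile 73.5) over 6 measured members, with MITF at -1.26 and PMEL at 0.92. Mesenchymal genes had a median of -0.01 (percentile 40.9), with PRRX1 at 1.96 and THY1 at -1.26, and epithelial and junction genes one of -0.25 (percentile 6.01), with KRT7 at -1.93 and OCLN at 0.91. Over the alternatives the epithelial median ran from -0.59 to 0.12 (percentile 0.26 to 61.5). Neuronal markers, of a cell type the labels do not name, had a median of 0.56 (percentile 98.3) over 6 members, with MAP2 at 1.68 and TUBB3, a neuronal tubulin, at -0.99 (4706 against 2358). Heat shock genes stood at 0.38 (percentile 96.6), with 7 of 9 members above 0, HSPA4L at 0.91 and HSPB1 at -1.32. MicroRNA machinery had a median of -0.04 (percentile 22.3), with DICER1 at -0.65. Medians were -0.14 for oxidative phosphorylation (percentile 5.10), -0.15 for ribosomal proteins (percentile 6.995) and 0.03 for membrane traffic (percentile 43.9). The median and the mean had opposite signs for centriole duplication (0.03 and -0.11), motile cilium genes (0.08 and -0.29), the ATF4 list (0.16 and -0.09) and mesenchymal genes (-0.01 and 0.27), none of which stood apart, and for some lists with both within 0.1 of 0.

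TLR3, an endosomal sensor of double-stranded RNA that interferon also induces, read 104 and 3020 on its brightest probe set, and was chosen after its values were seen.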
